A study of Escherichia coli with 96 samples.

How the data were processed

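RNA abundance was measured on 96 two-colour Agilent arrays of Escherichia coli MG1655, each with RNA exposed to CORM-3 or iCORM-3 in 1 channel and RNA of the same arm prior to addition in the other. There were 4 arms (aerobic or anaerobic, CORM-3 or iCORM-3) with 2 cultures each, 6 times and a dye swap at each time. The authors scanned the arrays with Agilent Feature Extraction 10.10.1.1. The deposited scanner files hold the median signal and the median local background of each spot as an intensity for both channels. Per the file headers they also hold the log10 ratio of red to green after background subtraction and dye normalization by that software. Other deposited columns are flags of 0 or 1 per spot, such as whether a spot was well above background or an outlier. The deposited value table is in log10 of exposed over prior RNA; it was checked against the scanner files and equals their log10 ratio, turned where the exposed RNA was in the green channel, to within 5e-06.

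Each array had 15744 spots, 556 of them controls, for 4598 probes. Probes were joined to genes by locus tag (4074), symbol (241) or synonym (42), which gave 4277 genes; 241 probes had no matching gene, of which 161 carried a retired locus tag, and stayed out of the gene tests. The genome build is not stated, so no coordinates were used. Median signals per array ran from 158 to 1173 in the exposed and from 73 to 1171 in the prior RNA, and at most 1 spot per array was saturated. The number of arrays, from 2 cultures per arm, limits the precision.

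Signals were background-corrected by normexp with an offset of 50 and normalized by loess within each array in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with control spots given no weight and outlier-marked spots set missing. Spots were averaged to probes and probes to genes, and the sign was set by the channel labels so that positive values mean more RNA after exposure. Probes had to be well above background in 1 channel on at least 4 of 96 arrays, which all did. In 4 arrays of anaerobic iCORM-3 the sample title and the channel labels disagree on the dyes; the channel labels were used. The dye-swap pair was averaged, then the 6 times, to give 1 value per culture, and the 8 culture values were fitted in limma with 4 arm means and moderated tests (eBayes). P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05, and tests were two-sided. The comparisons were the mean of each arm, CORM-3 minus iCORM-3 at each aeration and over both, aerobic minus anaerobic for each compound, the interaction, and late (20, 40 and 80 min) minus early (2.5, 5 and 10 min). Single times were tested in a limma fit of 48 values with 24 group means, with 24 residual degrees of freedom, which treats the times of a culture as independent. An alternative fit took the culture as a random block, with an estimated correlation of 0.46 within a culture. RNA before addition was compared from the prior channel after Aquantile normalization between arrays, averaged over the 12 arrays of each culture, 4 cultures against 4. All intervals are 95% intervals of the limma fit.

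The 35 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and members were also counted when adjusted over the list alone. The test with an estimated correlation rests on 8 culture values and 4 residual degrees of freedom, and no list passed it in any comparison. A call lost there does not decide whether a list changed. Gene lists, comparisons, the rule for naming genes and the alternatives were fixed before the data were examined, except 2 alternatives added after seeing the data, which left out the array pairs of negative dye-swap correlation and fitted the slide as a fixed block. The rule took, per arm, the 10 largest rises and 10 largest falls among called genes of the same sign in both cultures; for each other comparison the 5 largest each way; up to 4 members of each list with the largest change; and 20 genes always reported, which were spy, cpxP, zntA, znuA, zinT, copA, soxS, katG, ibpA, recA, metF, metE, cysK, cyoA, cydA, ytfE, hmp, iscR, entC and fliC. Genes plotted or followed over time come from these.

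The replicate numbers of the labels were tested as pairs: residual correlations of same-numbered cultures between arms ran from -0.14 to 0.31, so cultures were not paired. Alternatives tried were the deposited log10 ratio, the deposited value table, a normexp offset of 10, median centring, scale normalization between arrays, no filter, a filter on both channels in 48 arrays, the median over probes, the 4 conflicting arrays left out or turned, 2.5 or 80 min left out, each culture left out in turn, a replicate block, the slide as a block, eBayes with trend and robust, only 2 arms in the fit, a 2-fold minimum and quantile normalization of all channels for the RNA before addition. The pipeline was also tested on simulated data with 200 changed genes. With 2 cultures per arm, a change of 1 log2 unit in aerobic CORM-3 was recovered in 97.0% of such genes, and for CORM-3 minus iCORM-3 aerobically in 82.1%.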

Results

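RNA of Escherichia coli K-12 strain MG1655 grown in continuous culture in Evans medium was compared on 2-colour Agilent arrays before and after addition of 40 µM of a ruthenium compound. CORM-3, tricarbonylchloro(glycinato)ruthenium(II), releases carbon monoxide, and iCORM-3 is its inactivated form without releasable carbon monoxide. There were 4 arms, aerobic or anaerobic cultures given CORM-3 or iCORM-3, each with 2 cultures sampled at 2.5, 5, 10, 20, 40 and 80 min. Each sample was measured on a pair of dye-swap arrays against RNA taken from the same arm prior to addition, which gave 24 arrays per arm and 96 in all. Per array, 50.2 to 100% of spots were well above background in the exposed RNA (median 90.5%) and 62.4 to 100% in the prior RNA (median 91.0%), and the number of arrays, from 2 cultures per arm, limits the precision. The 4277 genes with a probe carry locus tags (b numbers), and no genome build is stated, so no positions are given. All changes are log2 ratios of exposed to prior RNA, averaged over the 6 times unless a time is named, with the SD over the 2 cultures. A gene is said to have risen or fallen, or to be called, at an adjusted p under 0.05 in limma over all genes. No untreated or vehicle time course was part of the design, so each change is relative to RNA prior to addition, and the 2 compounds are compared at the same dose and times. Each of the 12 slides and each of the 8 scan days held arrays of 1 arm only, so differences between arms cannot be told apart from slide or scan day.

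The first comparison asks how the cultures differed before any compound was added. RNA of the TCA cycle, cytochrome bo3 oxidase and NADH dehydrogenase I was lower in anaerobic than in aerobic cultures, and RNA of copper resistance and acid resistance genes was higher. These list calls were lost with an estimated correlation (adjusted p = 0.20 to 0.33). All 15 genes of the TCA cycle, all 5 of cytochrome bo3 oxidase and all 13 of NADH dehydrogenase I were lower anaerobically, with cyoA, a bo3 oxidase subunit, at -5.59 and actP, an acetate permease, at -5.15. Of 15 acid resistance genes, 14 were higher and 1 was lower, with gadE, an activator of acid resistance, at 3.94. Of 10 copper and silver resistance genes, 9 were higher, with the efflux components cusF at 4.73 and cusB at 4.70. The envelope stress genes cpxP and spy were also higher, by 2.52 and 1.51. The list counts were the same adjusted over the list alone, and the adjusted p with an estimated correlation was 0.20 for copper, 0.25 for NADH dehydrogenase, 0.30 for acid resistance and 0.33 for the TCA cycle and bo3 oxidase. In all, 1899 genes differed, 992 higher and 907 lower anaerobically (4 cultures against 4, limma), and 555 of them differed at least 2-fold.

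CORM-3 in aerobic cultures was asked about next, as the effect of the active compound where oxygen is respired. RNA of the Cpx envelope stress, Bae efflux and heat shock lists rose, and RNA of the TCA cycle, cytochrome bo3 oxidase and NADH dehydrogenase I fell. Every one of these list calls was lost with an estimated correlation (adjusted p = 0.16 to 0.28). That test has 4 residual degrees of freedom and passed no list in any comparison, so the loss does not decide whether these lists changed. The largest rise was in spy (b1743), which encodes a periplasmic chaperone, at 8.25 ± 0.20 (SD, n = 2; adjusted p = 3e-07 in limma). It was followed by yebE at 5.56 ± 0.55 (SD, n = 2), gcvB, a small RNA that represses amino acid uptake genes, at 5.50 ± 0.26 (SD, n = 2), and mdtA, a subunit of a multidrug efflux pump, at 5.49 ± 0.28 (SD, n = 2). The largest falls were in actP at -4.24, in acs, acetyl-CoA synthetase, at -4.14 ± 0.91 (SD, n = 2), and in sdhC, a succinate dehydrogenase subunit, at -3.97 ± 0.27 (SD, n = 2). In total 1813 genes were called, 829 up and 984 down, of which 463 changed at least 2-fold, and the 2 cultures' changes correlated across genes at 0.96.

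Among the fixed lists, all 15 Cpx envelope stress genes rose in aerobic cultures with CORM-3 (median 2.48), among them cpxP, an inhibitor of the Cpx sensor, at 5.30 ± 0.21 (SD, n = 2), and the periplasmic protease gene degP at 3.66 ± 0.13 (SD, n = 2). All 9 genes of the Bae efflux regulon rose, and so did 18 of 19 heat shock genes, including the chaperone genes dnaK at 1.88 ± 0.06 and groS at 1.77 ± 0.09 (SD, n = 2). Of 10 copper and silver resistance genes, 9 rose, with cusB at 3.05 ± 0.45 and the copper exporter gene copA at 2.61 ± 0.10 (SD, n = 2). Of 13 zinc homeostasis genes, 10 rose and 1 fell: znuA, for zinc uptake, was at 1.90 ± 0.07, while zntA, for zinc export, fell to -0.50 ± 0.06 (SD, n = 2). Of 30 cysteine and sulfur genes, 22 rose and 3 fell, and of 15 methionine genes 13 rose, with metF at 2.37 ± 0.03 (SD, n = 2). The genes that fell included 15 of 15 of the TCA cycle (median -2.56), 5 of 5 of cytochrome bo3 oxidase (median -3.19, cyoA at -3.75 ± 0.01, SD, n = 2) and 13 of 13 of NADH dehydrogenase I (median -1.08). In addition, 18 of 19 RpoS general stress genes fell, with osmY at -1.97 ± 0.18 (SD, n = 2), as did 12 of 15 acid resistance genes and 26 of 38 flagella and chemotaxis genes, with flagellin, fliC, at -1.56 ± 0.04 (SD, n = 2). Other stress, efflux and oxidase lists did not pass camera: of 16 multidrug efflux and MarA/Rob genes 3 rose and 2 fell, of 14 sigma E envelope stress genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; median -0.15, mean 0.07), and of 5 cytochrome bd oxidase genes 2 fell. Adjusted over the list alone, the counts rose to 14 for methionine, 23 for cysteine and sulfur and 28 falls for flagella, 1 acid resistance gene was then up, and the other lists here had the same counts. Apart from those 3, these lists passed camera with a preset correlation, and all lost the call with an estimated one: the adjusted p with an estimated correlation was 0.16 for Cpx, heat shock, copper, zinc, cysteine, RpoS and flagella, 0.20 for Bae, 0.27 for methionine and acid resistance, and 0.28 for the TCA cycle, bo3 oxidase and NADH dehydrogenase lists. Without aerobic CORM-3 replicate 1, 1009 genes were called, and the calls of zntA, metE, cysK, cydA, hmp and iscR each ended when 1 of the 8 cultures was left out, while the 10 largest rises and 10 largest falls kept theirs. With scale normalization between arrays, which evens out their spread, 1068 genes were called, and with median centring in place of loess 1294, 436 up and 858 down.

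CORM-3 in anaerobic cultures addressed the same question without oxygen to respire. Cpx, Bae and heat shock genes again rose, while RNA of the nitrogen limitation, arginine and pyrimidine and purine lists fell. With an estimated correlation none of these list calls held (adjusted p = 0.15 to 0.27). The largest rises were in spy at 6.52 ± 0.40 (SD, n = 2; adjusted p = 1.5e-06 in limma), mdtA at 5.31 ± 0.48 (SD, n = 2), mdtB at 4.17 and mdtC at 3.64. The largest falls were in glnA, glutamine synthetase, at -2.68 ± 0.27 (SD, n = 2; adjusted p = 4.5e-06 in limma), gatB, of galactitol uptake, at -2.59 ± 0.12 (SD, n = 2), pyrI, a subunit of aspartate transcarbamoylase, at -2.46 ± 0.21 (SD, n = 2), and argD, of arginine synthesis, at -2.44 ± 0.39 (SD, n = 2). In total 1469 genes were called, 681 up and 788 down, 285 of them at least 2-fold, and the 2 cultures' changes correlated across genes at 0.87.

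By list, 13 of 15 Cpx genes rose with CORM-3 in anaerobic cultures (14 adjusted over the list alone; median 1.64), as did 9 of 9 Bae genes (median 2.70) and 18 of 19 heat shock genes (median 1.34), with cpxP at 3.17 ± 0.40 and the small heat shock protein gene ibpA at 1.48 ± 0.08 (SD, n = 2). Of 30 cysteine and sulfur genes 24 rose and 1 fell (26 and 1 adjusted over the list alone), with the sulfate-binding protein gene sbp at 1.64 ± 0.34 (SD, n = 2), and 12 of 15 methionine genes rose (12 up and 1 down adjusted over the list alone). Of 10 copper and silver resistance genes 6 rose, with copA at 1.15 ± 0.24 (SD, n = 2), and of 7 phage shock genes 6 rose, with pspA at 0.95. In the other direction, 15 of 16 arginine genes fell (median -1.66), as did 19 of 20 pyrimidine and purine genes, of which 1 rose (median -1.18), with carA, a subunit of carbamoyl phosphate synthetase, at -2.31 ± 0.37 (SD, n = 2). Of 15 nitrogen limitation genes 12 fell (13 adjusted over the list alone), among them glnH, a glutamine-binding protein gene, at -2.34 ± 0.03 (SD, n = 2). Of 15 acid resistance genes 14 fell (gadA at -2.10 ± 0.13, SD, n = 2), as did 13 of 13 NADH dehydrogenase I genes and 6 of 15 TCA cycle genes. The counts adjusted over the list alone were the same for Bae, heat shock, arginine, pyrimidine and purine, acid resistance and NADH dehydrogenase genes. With an estimated correlation, no list kept its call: the adjusted p was 0.15 for Cpx, heat shock, cysteine, acid resistance and pyrimidine and purine, 0.19 for Bae, 0.21 for copper, 0.22 for methionine, 0.23 for nitrogen, 0.27 for arginine and phage shock, 0.29 for NADH dehydrogenase and 0.49 for the TCA cycle. With scale normalization 936 genes were called and pyrI lost its call, and zntA, cysK, cydA, iscR and entC each lost theirs when 1 of the 8 cultures was left out. Several genes named elsewhere were dim on these arrays: acs was well above background on 6 of 24 arrays in the exposed RNA and zinT on 6 of 24 in the prior RNA, so their anaerobic CORM-3 values are not given.

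The responses to CORM-3 with and without oxygen were then compared directly. Of the genes called in both, 919 in number, 798 changed in the same direction, and 406 rose in both where 132 would be shared by chance. The direct test called 1056 genes, 463 more positive and 593 more negative in aerobic cultures. With the deposited log10 ratio it called 1075, 548 more positive and 527 more negative, so the balance of directions depends on the processing. All 15 TCA cycle genes and all 5 bo3 oxidase genes fell further aerobically, with sdhC at a difference of -3.32 (95% interval -4.50 to -2.14). In anaerobic cultures sdhC was at -0.65 ± 1.37 (SD, n = 2), with an adjusted p of 0.20 in limma. All 16 arginine genes and 18 of 20 pyrimidine and purine genes (19 adjusted over the list alone) were more positive aerobically, with glnA different by 3.36 and argD by 3.09. The copper efflux gene cusB rose aerobically and was at 0.22 ± 0.13 (SD, n = 2) anaerobically, a difference of 2.83. Before addition cusB was already higher anaerobically, at 13.1 against 8.43 aerobically on the log2 signal scale. Its difference in response therefore cannot be told apart from the difference in starting level. Of 38 flagella genes, 25 were more negative aerobically (27 adjusted over the list alone), with fliC at a difference of -1.61. Before addition 28 of these 38 genes, and all of the TCA cycle and bo3 oxidase genes, were already lower anaerobically, and flhD and fliA were dim in both channels on all 24 anaerobic CORM-3 arrays, so that a fall there was harder to detect. These list calls were lost with an estimated correlation (adjusted p = 0.36 for arginine, 0.44 for the TCA cycle and 0.20 for flagella and for pyrimidine and purine). Without aerobic CORM-3 replicate 1 the direct test called 639 genes, with scale normalization 536 and with median centring 683.

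iCORM-3 in aerobic cultures was examined for what changed after addition of the compound without releasable carbon monoxide. RNA of the glycine cleavage system and of gcvB rose, and few other single genes passed the test. The rises were in gcvB at 2.88 ± 0.11, gcvH at 2.32 ± 0.04, gcvT at 2.24 ± 0.15 and gcvP at 1.85 ± 0.11 (SD, n = 2), with adjusted p from 6.5e-05 to 0.00016 in limma. These were followed by metB at 1.27 ± 0.35 (SD, n = 2), sdaA, a serine deaminase, at 0.88, mmuP at 0.80 and metL at 0.80, and ygfF was at 0.64. The falls were in the binding proteins for branched-chain amino acids, livJ, at -0.98 ± 0.17 and for dipeptides, dppA, at -0.59 ± 0.11 (SD, n = 2). These 11 genes were all that passed, 9 up and 2 down, while 307 had an unadjusted p under 0.05. Of 15 methionine genes 3 rose, 13 when adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). In all, 19 of 35 lists passed camera with the preset correlation, 16 up and 3 down, and all 19 calls were lost with an estimated correlation. Adjusted over the list alone, 11 of 16 arginine, 12 of 30 cysteine and sulfur, 6 of 8 histidine and 4 of 15 Cpx genes rose and 11 of 15 acid resistance genes fell, where limma over all genes called none of them; the adjusted p with an estimated correlation was 0.21, 0.12, 0.18, 0.18 and 0.15. The Cpx genes spy and cpxP did not pass over all genes: spy was at 0.62 ± 0.32 and cpxP at 0.70 ± 0.55 (SD, n = 2), with adjusted p of 0.51 and 0.31 in limma. The 2 cultures correlated at 0.39 across genes and the median dye-swap correlation was 0.24, with 2 pairs below 0. Without aerobic iCORM-3 replicate 2, 4 genes were called, with either aerobic CORM-3 culture left out 19 were, with 80 min left out 23, with scale normalization 84 and with the slide as a random block 97, and the 4 gcv genes kept their calls without each culture in turn, while metB, sdaA, mmuP, metL, ygfF, livJ and dppA did not. With the 4 arrays of anaerobic iCORM-3 whose labels conflict turned as titled, gcvB lost its call, and gcvT, gcvH and gcvP kept theirs.

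After addition of iCORM-3 to anaerobic cultures, gcvB, gcvT and gcvH rose together with genes of the Cpx and nitrogen limitation lists. The galactitol uptake gene gatB and the mannose uptake gene manX were among those that fell. Neither list call held with an estimated correlation (adjusted p = 0.18 for Cpx and 0.31 for nitrogen limitation). In 4 of the 24 arrays of this arm, those of 1 culture at 10 to 80 min on 1 slide, the sample titles and the channel labels disagree on the dyes. The channel labels were used, under which those 4 pairs had dye-swap correlations of 0.739 to 0.823. Turned as the titles say, each of these arrays cancels its dye-swap partner, and 0 genes in this arm passed limma (536 at an unadjusted p under 0.05). With the 4 arrays left out, 409 genes were called, 334 of them among the 338 called with all arrays and in the same direction. The largest rises were in spy at 2.54 ± 0.63 (SD, n = 2; adjusted p = 0.00049 in limma), gcvB at 2.30 ± 0.39, gcvT at 2.13 ± 0.26, gcvH at 1.83 ± 0.19 and metB at 1.49 ± 0.50 (SD, n = 2). Among the largest falls were the galactitol genes gatC at -1.88, gatZ at -1.86 and gatB at -1.86 ± 0.19 (SD, n = 2). The mannose uptake gene manX was at -1.76 ± 0.01 (SD, n = 2). Galactitol and mannose genes were not tested as lists. In total 338 genes were called, 127 up and 211 down, 44 of them at least 2-fold.

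Of 15 Cpx genes 13 rose with iCORM-3 in anaerobic cultures (median 0.69), with cpxP at 1.21 ± 0.06 (SD, n = 2), and 6 of 9 Bae genes rose, 8 adjusted over the list alone. Of 15 methionine genes 11 rose (13 adjusted over the list alone), and of 15 nitrogen limitation genes 7 rose (9 adjusted over the list alone), with glnA at 1.26 ± 0.22 and glnH at 1.27 ± 0.18 (SD, n = 2). Of 9 ATP synthase genes 6 rose, and all 9 did when adjusted over the list alone. Of 19 heat shock genes 2 rose, and ibpA was at 0.09. Of 15 acid resistance genes 13 fell (14 adjusted over the list alone), and of 19 RpoS genes 13 fell (17 adjusted over the list alone), with osmY at -1.04 ± 0.00 (SD, n = 2). The adjusted p with an estimated correlation was 0.18 for Cpx, acid resistance and RpoS, 0.22 for methionine, 0.27 for Bae and ATP synthase and 0.31 for nitrogen. Without anaerobic iCORM-3 replicate 1, 77 genes were called, and without replicate 2, 56 were; metF, yhdV, yebE and cpxP lost their calls in 1 or both of these. Of 62 called list members 15 kept the call with each culture left out in turn, as did 2 of 5 called genes among those always reported. With median centring 199 genes were called, and with scale normalization 612.

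The 2 iCORM-3 arms differed in 22 genes, 16 more positive and 6 more negative aerobically. The uptake genes gatB and manX differed by 1.74 and 1.73, and the glutamine transport genes glnQ and glnH by -1.44 and -1.35. The difference in spy was -1.92 (adjusted p = 0.046 in limma), and it did not pass without either aerobic CORM-3 culture, without either aerobic iCORM-3 culture, without anaerobic iCORM-3 replicate 2, with 80 min left out or with scale normalization. The count lay between 7 and 40 as single cultures were left out, the lowest without anaerobic iCORM-3 replicate 2 and the highest without either anaerobic CORM-3 culture. It was 120 with scale normalization, 172 with the slide as a random block and 51 with only these 2 arms in the fit. Turning the 4 arrays as titled left 0 genes past limma, with 154 at an unadjusted p under 0.05, while leaving them out gave 26, of which 21 were among the 22.

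CORM-3 was then compared with iCORM-3, the form without releasable carbon monoxide, at the same dose and times. No arm received carbon monoxide alone, so differences between the compounds cannot be credited to carbon monoxide by itself. In aerobic cultures, Cpx, Bae and heat shock RNA was higher with CORM-3, and TCA cycle, bo3 oxidase and NADH dehydrogenase I RNA lower, list calls that did not hold with an estimated correlation (adjusted p = 0.12 to 0.27). The difference was 7.63 for spy (95% interval 6.92 to 8.33), 5.23 for mdtA (4.67 to 5.79), 4.60 for cpxP (3.99 to 5.22) and 2.42 for copA (2.11 to 2.73). It was -4.01 for sdhC (-5.18 to -2.83), -3.79 for acs (-5.09 to -2.49), -3.71 for cyoA (-4.56 to -2.87) and -1.62 for fliC (-1.87 to -1.37). All 15 Cpx and all 9 Bae genes were higher with CORM-3, with 16 of 19 heat shock genes (18 adjusted over the list alone) and 8 of 10 copper genes (9 adjusted over the list alone). All 15 TCA cycle, 5 bo3 oxidase and 13 NADH dehydrogenase genes were lower, as were 23 of 38 flagella genes (25 adjusted over the list alone). Estimated correlation ended these list calls (adjusted p = 0.12 for Cpx and copper, 0.15 for Bae, heat shock and flagella, 0.27 for the TCA cycle, bo3 oxidase and NADH dehydrogenase). In all 1050 genes differed, 392 higher and 658 lower with CORM-3, and 393 differed at least 2-fold. Without aerobic CORM-3 replicate 1, 651 genes were called, without aerobic iCORM-3 replicate 2, 682, and with scale normalization 503.

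Several aerobic genes were not told apart between the compounds. The difference was -0.17 for metE (95% interval -1.06 to 0.72), -0.05 for cysK (-0.44 to 0.33), 0.03 for recA, of DNA repair (-0.25 to 0.31), and 0.25 for entC, of enterobactin synthesis (-0.14 to 0.64). It was -0.61 for katG, catalase (-1.06 to -0.15; adjusted p = 0.058 in limma) and -0.61 for cydA, of the bd oxidase (-1.17 to -0.05; adjusted p = 0.11 in limma). For metF the difference was 1.15 (0.49 to 1.80; adjusted p = 0.021 in limma), a call that ended without aerobic CORM-3 replicate 1.

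In anaerobic cultures, CORM-3 minus iCORM-3 again showed higher Bae, Cpx and heat shock RNA, while nitrogen, arginine and pyrimidine RNA was lower with CORM-3, list calls that did not hold with an estimated correlation (adjusted p = 0.13 to 0.28). The difference was 4.12 for mdtA (95% interval 3.56 to 4.68), 3.98 for spy (3.27 to 4.69), and 1.95 for cpxP (1.34 to 2.57). It was -3.94 for glnA (-4.36 to -3.52), -2.55 for pyrI (-3.83 to -1.26) and -2.41 for argD (-3.16 to -1.66). Of the list members, 12 of 15 Cpx (12 and 1 lower adjusted over the list alone), 8 of 9 Bae (9 adjusted over the list alone) and 18 of 19 heat shock genes were higher with CORM-3. Lower were 12 of 15 nitrogen, 14 of 16 arginine and 18 of 20 pyrimidine and purine genes (19 adjusted over the list alone). The adjusted p with an estimated correlation was 0.13 for Cpx, heat shock and pyrimidine and purine, 0.20 for Bae and nitrogen and 0.28 for arginine. In all 765 genes differed, 366 higher and 399 lower with CORM-3, and 209 at least 2-fold. Not told apart were metF at 0.16 (-0.50 to 0.82), metE at -0.25 (-1.14 to 0.64), fliC at 0.14 (-0.10 to 0.39), soxS at -0.29 (-0.64 to 0.06) and sdhC at -1.24 (-2.42 to -0.07; adjusted p = 0.14 in limma). Without anaerobic iCORM-3 replicate 1, 381 genes were called, without replicate 2, 476, with median centring 425 (221 higher, 204 lower), with scale normalization 458 (257 higher, 201 lower) and with only these 2 arms in the fit 496. Of 95 called list members 54 kept the call with each culture left out in turn and 47 under the other settings. The calls of pyrI and, with scale normalization, spy and cpxP ended in some of these.

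Averaged over both aerations, CORM-3 differed from iCORM-3 in 1266 genes, 554 higher and 712 lower, led by spy at 5.80 (95% interval 5.30 to 6.30), mdtA at 4.67, mdtB at 3.80 and yebE at 3.68. Among the genes lower with CORM-3 were glnH at -2.92 (-3.13 to -2.70) and glnQ at -2.89. With scale normalization 597 genes were called and with median centring 821. Whether the difference between compounds itself depended on oxygen was tested as an interaction, which called 727 genes, 289 more positive and 438 more negative aerobically. It called 466 genes without aerobic iCORM-3 replicate 1, 483 without replicate 2, 434 with scale normalization, 478 with median centring and 1133 with the slide as a random block. The interaction was 3.89 for glnA (3.29 to 4.48), 3.65 for spy (2.65 to 4.65), 2.47 for cusB (1.83 to 3.11), -2.89 for sdhA (-3.95 to -1.84) and -1.77 for fliC (-2.12 to -1.41). For mdtA it was 1.11 (0.31 to 1.91; adjusted p = 0.064 in limma), which did not pass. Of the lists, 13 of 15 Cpx genes (14 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation) were more positive and all 15 TCA cycle genes (adjusted p = 0.41 with an estimated correlation) more negative aerobically. Before addition 13 of 15 Cpx genes were already higher and all 15 TCA cycle genes lower anaerobically. At that point spy was at 9.13 aerobically and 10.6 anaerobically on the log2 signal scale, and cusB at 8.43 and 13.1. An oxygen-dependent response to the compounds therefore cannot be told apart from these starting levels. The spy interaction ended with the 4 conflicting arrays turned as titled.

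**Figure D1:**
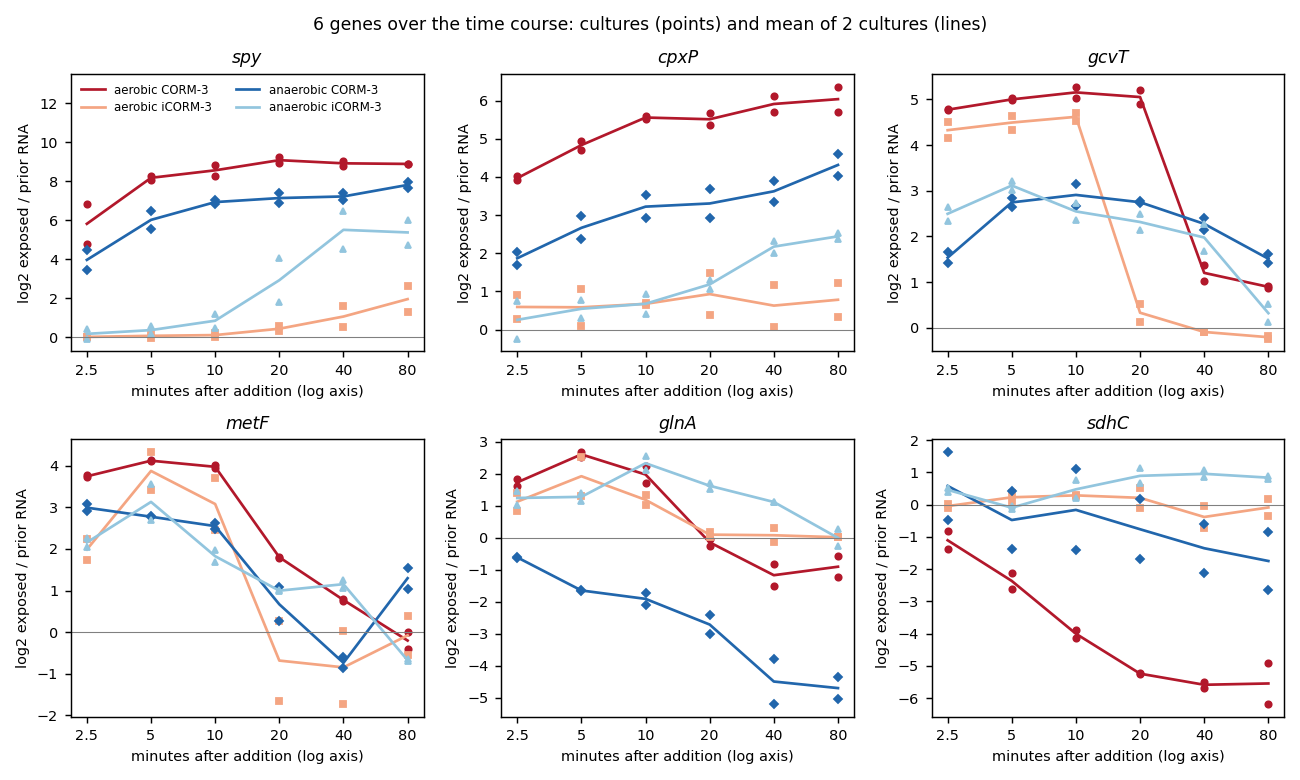
Log2 ratio of exposed to prior RNA for 6 genes (spy, cpxP, gcvT, metF, glnA and sdhC) against minutes after addition on a log axis. Points are the cultures and lines the mean of 2 cultures in each of the 4 arms; spy with CORM-3 in aerobic cultures is at 5.83 at 2.5 min and 8.89 at 80 min.

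The time course asked when each response arose. With CORM-3, spy was already high at 2.5 min, at 5.83 ± 1.45 aerobically and 3.98 ± 0.75 anaerobically, and at 80 min it was 8.89 ± 0.02 and 7.82 ± 0.20 (SD, n = 2). With iCORM-3 in anaerobic cultures spy was at 0.19 ± 0.35 at 2.5 min and 5.52 ± 1.35 at 40 min (SD, n = 2). With iCORM-3 in aerobic cultures it reached 1.97 ± 0.93 at 80 min (SD, n = 2; adjusted p = 0.060 in limma). gcvT was at 4.32 ± 0.26 at 2.5 min and 4.62 ± 0.13 at 10 min with iCORM-3 aerobically, and at 0.33 ± 0.27 at 20 min (SD, n = 2). With CORM-3 aerobically gcvT was still at 5.05 at 20 min and at 1.20 at 40 min. With CORM-3 aerobically sdhC was at -1.11 at 2.5 min (adjusted p = 0.22 in limma), and it fell to -5.24 at 20 min and -5.54 at 80 min. glnA rose aerobically with CORM-3 to 2.61 at 5 min and was at -1.17 at 40 min, while anaerobically it went from -0.61 at 2.5 min to -4.70 at 80 min. baeS, the Bae sensor kinase gene, was at -0.17 at 5 min and 3.87 at 10 min aerobically with CORM-3, and at -0.05 and 3.71 anaerobically.

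**Figure D2:**
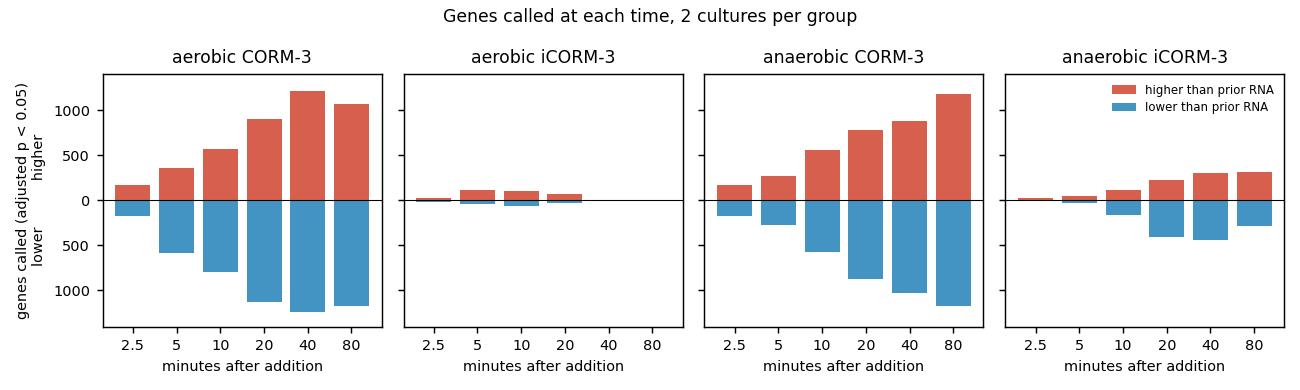
Number of genes called higher and lower at each time after addition in each of the 4 arms (limma, adjusted p under 0.05). With CORM-3 in aerobic cultures the total is 335 at 2.5 min and 2456 at 40 min, and with iCORM-3 in aerobic cultures it is 159 at 10 min and 5 at 80 min. Dye-swap correlations of aerobic iCORM-3 replicate 2 were below 0 at 40 and 80 min.

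Genes called per time, from 2.5 to 80 min, numbered 335, 939, 1365, 2030, 2456 and 2241 with CORM-3 aerobically and 348, 545, 1133, 1653, 1905 and 2355 anaerobically. With iCORM-3 they numbered 38, 155, 159, 105, 0 and 5 aerobically and 27, 76, 281, 639, 743 and 600 anaerobically. At the time with 0 calls, 247 genes had an unadjusted p under 0.05 in limma. At 40 and 80 min the aerobic iCORM-3 cultures correlated at 0.07 and 0.16, against 0.81 and 0.76 anaerobically. Replicate 2 of aerobic iCORM-3 had dye-swap correlations of -0.11 and -0.21 at these times. The low counts there thus do not tell a response that ended from noisy arrays. The compounds differed in 85, 327, 871, 1428, 1754 and 1601 genes aerobically and in 98, 302, 700, 893, 1150 and 1549 anaerobically. With the culture as a random block 35 of these 36 counts stayed within 1.5 times, and anaerobic iCORM-3 at 5 min fell from 76 to 49. These counts fell by more than 1.5 times in 27 of 36 cases with median centring, in 13 with scale normalization, which raised 10, and in 13 without anaerobic iCORM-3 replicate 1. At matched times, gcvT was not told apart between the compounds aerobically up to 10 min, with a difference of 0.45 (95% interval 0.04 to 0.86; adjusted p = 0.44 in limma) at 2.5 min and 0.53 (0.12 to 0.94; adjusted p = 0.058 in limma) at 10 min, and differed by 4.72 (4.31 to 5.13) at 20 min. Anaerobically, spy differed by 6.08 at 10 min and by 1.71 (adjusted p = 0.043 in limma) at 40 min, and glnA by -1.86 at 2.5 min and -5.61 at 40 min. cysK, which did not differ on average, differed aerobically by -1.58 at 10 min and by 2.05 at 80 min.

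The mean of 20, 40 and 80 min minus that of 2.5, 5 and 10 min was called in 1945 genes with CORM-3 aerobically, 1840 anaerobically, and in 66 and 425 genes with iCORM-3. Methionine RNA was early in every arm: 15 of 15 genes were lower late with CORM-3 aerobically and 14 of 15 in each of the other 3 arms. With CORM-3 aerobically the phosphate-binding protein gene pstS was higher late by 3.89 and baeS by 3.63, and the galactose-binding protein gene mglB was lower late, at -4.58. Anaerobically with CORM-3, 19 of 19 heat shock genes were higher late and all 16 arginine genes lower. With iCORM-3 aerobically gcvB and gcvT were lower late, at -4.64 and -4.47. With iCORM-3 anaerobically spy was higher late by 4.14 and 13 of 15 Cpx genes were higher late (14 adjusted over the list alone). The other list counts here were the same adjusted over the list alone. The adjusted p with an estimated correlation was 0.24 to 0.32 for methionine, 0.22 for heat shock, 0.29 for arginine and 0.19 for Cpx. Early and late arrays of 1 arm shared slides, and within each of the 12 slides spy was higher late, by 0.54 to 5.41, and metF lower late, at -4.11 to -1.45. The late rise of spy with CORM-3 is the exception under scale normalization, where it became -1.32 aerobically and -0.57 anaerobically. Without 1 culture of their own arm the iCORM-3 counts were at lowest 24 aerobically (without replicate 1) and 84 anaerobically (without replicate 2), and without anaerobic CORM-3 replicate 1 that arm had 1107. The aerobic CORM-3 count was 1237 without replicate 1, the aerobic iCORM-3 count 166 with 2.5 min left out, and the anaerobic iCORM-3 count 16 with the 4 conflicting arrays turned and 473 with them left out, which included 405 of the 425.

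**Figure D3:**
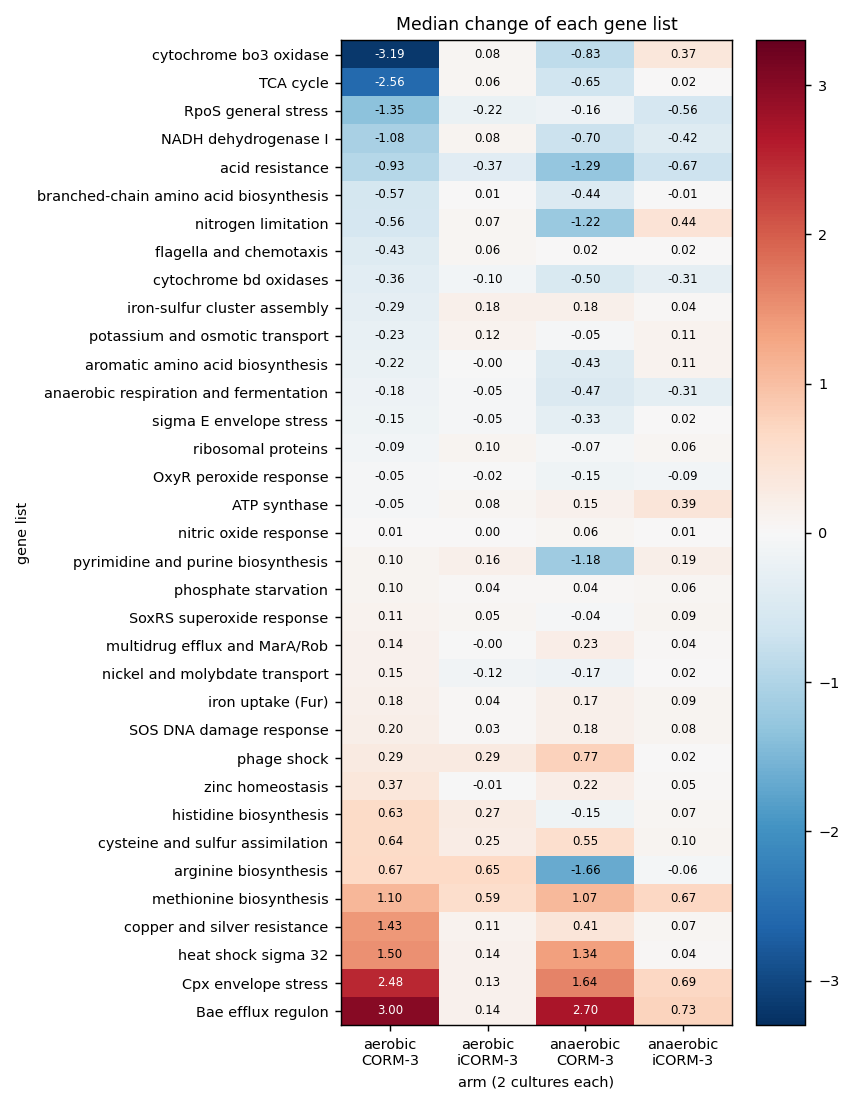
Median log2 ratio of exposed to prior RNA, mean over the 6 times, for each of 35 gene lists in the 4 arms. With CORM-3 aerobically the Cpx list is at 2.48 and the TCA cycle list at -2.56.

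How alike the arms were was measured by correlations across all 4277 genes, which are not independent replicates. The Pearson (and Spearman) correlation was 0.63 (0.53) between aerobic and anaerobic CORM-3, 0.47 (0.36) between the 2 iCORM-3 arms, 0.43 (0.30) between the 2 compounds aerobically and 0.45 (0.28) anaerobically. It was 0.54 (0.52) between aerobic CORM-3 and anaerobic iCORM-3 and 0.18 (0.04) between aerobic iCORM-3 and anaerobic CORM-3. Between the 2 cultures of an arm it was 0.96 (0.90) for aerobic and 0.87 (0.73) for anaerobic CORM-3. For iCORM-3 it was 0.39 (0.12) aerobically and 0.65 (0.28) anaerobically. This lower agreement limits how high correlations with the iCORM-3 arms can be, so the values do not rank the arms by likeness alone. All 11 genes called with iCORM-3 aerobically were also called with CORM-3 aerobically, in the same direction. Of 301 genes called both with CORM-3 aerobically and iCORM-3 anaerobically, 292 changed in the same direction, and of 261 called with both compounds anaerobically, 229 did.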

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

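Of the tests in this part, those of drift, dye bias, exchanged RNA, leftover CORM-3 and late array quality were chosen after the results were seen.

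Among 88 groups of 4 values, 7 held a value apart from the rest, where chance gives about 1 in 20. For the percentage of spots well above background in the exposed RNA, 1 of 4 arrays stood apart at 80.3% (aerobic CORM-3, 5 min), at 73.1% (aerobic CORM-3, 40 min), at 84.4% (aerobic iCORM-3, 40 min) and at 96.7% (anaerobic iCORM-3, 2.5 min). For spots marked as outliers, 1 of 4 arrays stood apart with 555 (aerobic iCORM-3, 2.5 min) and with 622 (anaerobic iCORM-3, 2.5 min), each the lowest of its group. The highest count on any array, 2636, was in anaerobic iCORM-3 at 10 min (replicate 2). That array had 61.5% of spots well above background in the exposed RNA. It was not flagged, since another array of its group had 1056. The level of cusF before addition stood apart in 1 of 4 anaerobic cultures, at 14.1 on the log2 scale.

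Responses differed with oxygen in 1056 genes for CORM-3 and in 22 for iCORM-3, and the difference between the compounds differed with oxygen in 727. Of the 241 probes with no matching gene, which the comparisons leave out, limma called 49 with CORM-3 aerobically (20.3%, against 42.4% of genes; largest rise 5.41), 29 with CORM-3 anaerobically (12.0%, against 34.3%; largest rise 3.22), 3 with iCORM-3 anaerobically (1.24%, against 7.90%) and 0 with iCORM-3 aerobically, where 9 had an unadjusted p under 0.05.

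For 2 counts, other splits of the 8 cultures into 4 and 4 were also fitted. For CORM-3 minus iCORM-3 in a fit of 2 groups, 1 of 35 splits, the real one, gave as many genes: 498, against at most 1 in the others. For anaerobic minus aerobic before addition it was also 1 of 35, with 1363 genes against at most 0 in the others. A share of 1 of 35 is the smallest that these splits can give. Each other split also puts the real difference into the spread, which lowers its count, so chance is not excluded. Slide and scan day go with the arms and could give the same result.

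The glycine cleavage genes and gcvB rose early with both compounds. Slow drift without any compound is argued against in aerobic cultures, where the mean of gcvT, gcvH and gcvP at 2.5 min was already 73.5% of its highest value in the lower of the 2 arms. In anaerobic cultures that share was 32.8%, which does not decide. There the mean was highest at 5 min with iCORM-3 (2.74 ± 0.08) and at 10 min with CORM-3 (2.66 ± 0.43; SD, n = 2). At 80 min it was 0.26 ± 0.17 and 1.20 ± 0.02 (SD, n = 2). An early peak followed by this decline argues against slow drift over the 80 min for these genes. Dye bias is argued against by the lowest gcvT value on any single iCORM-3 array at 2.5 to 10 min, 2.19, positive in both dye orientations. A response to handling at the addition itself stays open and was not tested, since no vehicle arm exists, and glycine from the compounds is taken up under the other observations.

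Nitrogen, arginine and pyrimidine genes were lower with CORM-3 than with iCORM-3 in anaerobic cultures. An exchange of exposed and prior RNA on the CORM-3 arrays is argued against by spy, whose lowest value on the 24 arrays was 3.33. Different levels before addition stay open: over the 44 called genes of the 3 lists, higher prior levels in the CORM-3 cultures matched a median of 25.0% of the difference, with quartiles of 1.29 and 38.3% and 6 genes over 50%. The limit set beforehand for arguing against this was a median under 25%, which 24.99% meets by a narrow margin. The test was instead read by the quartiles, which leave it open. Shares were 93.5% for nac and 87.2% for glnK, of nitrogen limitation, but 1.62% for argG and -2.36% for pyrB. What keeps it open is this spread of the shares over the genes, and that each slide held 1 arm only. A biological effect of releasable carbon monoxide without oxygen remains among the open explanations, untested.

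Cpx envelope stress genes rose late with iCORM-3 in anaerobic cultures. Leftover active CORM-3 giving its whole response in proportion is argued against by heat shock genes, whose late median was 8.85% of that with CORM-3, against 57.4% for Cpx genes. This covers only a response in proportion. Leftover CORM-3 that changed some lists more than others was not tested and stays open. Low quality of the late aerobic iCORM-3 arrays as the reason for the lower aerobic values stays open: without the pairs of negative dye-swap correlation spy was at 0.91 over 40 and 80 min, against 4.64 in the lower of the anaerobic cultures, but this leaves 1 aerobic culture, the one with the lower spy, whose pairs have dye-swap correlations of 0.275 and 0.167. The difference in oxygen, and the slides that go with it, stay open too.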

How the results depend on the processing

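Leaving out the array pairs of negative dye-swap correlation and fitting the slide as a fixed block were chosen after seeing the data; the other alternatives were planned. Of 28732 values of named genes under alternatives, 26356 kept direction and side of the threshold, 2079 lost the call, 113 gained one, 173 without a call changed sign and 11 reversed; of 369 counts over times or between arms, 289 stayed within 1.5 times, and so did 601 of 720 counts at single times; of the 36 single-time counts, median centring lowered 27 and scale normalization lowered 13 and raised 10 by more than that. These totals include no filter and the median over probes, which each left all 1120 values of named genes the same. They also count the processed log ratio and the value table separately, although these hold the same ratios. The shares that stayed alike are therefore raised by alternatives that could change little or nothing. The processed log ratio and the value table each gave 5 genes for aerobic iCORM-3. Median centring gave 1294 for aerobic CORM-3 (436 up, 858 down), 199 for anaerobic iCORM-3, 425 for CORM-3 minus iCORM-3 anaerobically, 683 for aerobic minus anaerobic CORM-3, 821 over both aerations and 478 for the interaction. Scale normalization, which evens the spread of arrays by construction, gave 1068 (aerobic CORM-3), 84 (aerobic iCORM-3), 936 (anaerobic CORM-3), 612 (anaerobic iCORM-3), 503 and 458 (CORM-3 minus iCORM-3, aerobic and anaerobic), 536 and 120 (aerobic minus anaerobic, CORM-3 and iCORM-3), 597 over both aerations, 434 for the interaction, and for late minus early 875 and 309 aerobically and 751 for anaerobic CORM-3. With it 11 values reversed: CORM-3 minus iCORM-3 anaerobically nuoE 0.0244, livJ 0.0496 and gadB 0.0436; over both aerations metF -0.11 and sufA 0.14; late minus early with CORM-3 spy -1.32, cpxP -0.85 and znuA -0.16 aerobically and spy -0.57, cpxP -0.0469 and znuA -0.0533 anaerobically. The 4 conflicting arrays turned as titled gave 7 for aerobic iCORM-3, 0 for anaerobic iCORM-3 (536 at an unadjusted p under 0.05 in limma), 0 for aerobic minus anaerobic iCORM-3 (154 unadjusted), late minus early 42 aerobically and 16 anaerobically with iCORM-3, and a correlation of 0.47 between aerobic CORM-3 and anaerobic iCORM-3; turned arrays cancel their partners. Left out instead, they gave 409 for anaerobic iCORM-3 (334 of the 338 shared), 26 for aerobic minus anaerobic iCORM-3 (21 of the 22 shared) and 473 late minus early in anaerobic iCORM-3 (405 of the 425 shared). Without the pairs of negative dye-swap correlation aerobic iCORM-3 had 7 genes and 34 late minus early. Without 2.5 min late minus early in aerobic iCORM-3 had 166; without 80 min aerobic iCORM-3 had 23 genes and the correlation above was 0.51. With trend and robust eBayes there were 4 for aerobic iCORM-3 and 13 for aerobic minus anaerobic iCORM-3. With only the 2 arms compared there were 496 for CORM-3 minus iCORM-3 anaerobically and 51 for aerobic minus anaerobic iCORM-3. With the 96 arrays fitted and the slide as a random block there were 97 and 541 for aerobic and anaerobic iCORM-3. Their difference had 172, the interaction 1133, and late minus early in these 2 arms 363 and 910. With the slide fixed these last were 364 and 938. Both fits take dye swaps and times of 1 culture as replicates, so their higher counts rest on no more cultures. Requiring 2-fold gave, by construction, 463, 5, 285 and 44 in the arms (CORM-3 then iCORM-3, aerobic then anaerobic), 393 and 209 between compounds, 317 for aerobic minus anaerobic CORM-3, 214 over both aerations, 382 for the interaction, 372, 30, 309 and 65 late minus early and 555 before addition. Camera with an estimated correlation, which rests on 4 residual degrees of freedom, called 0 lists. With the preset one 167 list tests passed over the comparisons of mean changes other than the interaction, and 17 for the interaction. List tests of late minus early and of RNA before addition are not in these counts. The causes of the other changes were not tested.

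With each culture left out, where the lone culture of an arm is assumed to vary like the others, counts ran from 1009 to 1898 (aerobic CORM-3), 4 to 19 (aerobic iCORM-3), 1037 to 1438 (anaerobic CORM-3), 56 to 420 (anaerobic iCORM-3), 651 to 1151 and 381 to 766 (CORM-3 minus iCORM-3, aerobic and anaerobic), 639 to 1023 and 7 to 40 (aerobic minus anaerobic, CORM-3 and iCORM-3), 893 to 1303 (both aerations), 466 to 770 (interaction), and late minus early 1237 to 2086, 24 to 76, 1107 to 1857 and 84 to 504. Genes called at any time ran from 3174 to 3487, between compounds 2448 to 2879, and before addition 1406 to 1866. Correlations between arms ran from 0.32 to 0.45 (aerobic CORM-3 and iCORM-3), 0.56 to 0.66 (CORM-3), 0.49 to 0.56 (aerobic CORM-3 and anaerobic iCORM-3), 0.12 to 0.20 (aerobic iCORM-3 and anaerobic CORM-3), 0.37 to 0.47 (iCORM-3) and 0.36 to 0.46 (anaerobic). The no-filter alternative removed no probe and so tested nothing. Genes dim in the anaerobic CORM-3 arrays, such as flhD and fliA on all 24, limit what can be said of them there.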

Other observations

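The GcvB target test in aerobic cultures was fixed before its result was seen, and those in anaerobic cultures after.

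Other amino acid lists moved with CORM-3, in both directions. Of 8 histidine genes 7 rose aerobically (7 adjusted over the list alone; median 0.63; adjusted p = 0.28 with an estimated correlation), while 2 fell anaerobically (3 adjusted over the list alone). Of 16 branched-chain amino acid genes 13 fell aerobically (adjusted p = 0.16 with an estimated correlation), with ilvC at -1.89 ± 0.53 (SD, n = 2), and 9 fell and 1 rose anaerobically (10 and 1 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), with ilvC at -1.46 ± 0.09 (SD, n = 2). Of 21 aromatic amino acid genes 10 fell and 1 rose aerobically (11 and 1 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), and 13 fell and 1 rose anaerobically (15 and 1 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), with aroG, a first enzyme of the pathway, at -2.13 ± 0.13 (SD, n = 2). The taurine transport gene tauA rose with CORM-3, to 1.15 ± 0.03 aerobically and 1.79 ± 0.20 anaerobically (SD, n = 2).

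Oxidative and nitrosative stress genes moved in both directions. soxS, a superoxide response regulator, rose with CORM-3 aerobically (1.07 ± 0.09, SD, n = 2), with CORM-3 anaerobically (0.69 ± 0.08) and with iCORM-3 anaerobically (0.98 ± 0.30), while katG, catalase, fell in the same arms, to -0.83, -0.89 and -0.79. The call of katG with iCORM-3 anaerobically ended without either culture of that arm, and those of both genes there ended with the 4 conflicting arrays turned as titled. Of 16 SoxRS genes 2 rose and 3 fell with CORM-3 aerobically, where the list's median was 0.11 and its mean -0.06. Of 13 nitric oxide genes 2 rose and 4 fell there, with hmp, flavohemoglobin, at -0.39 ± 0.09 and ytfE at -0.58 ± 0.26 (SD, n = 2); the list's median was 0.01 and its mean -0.07. Of 21 SOS genes 8 rose and 3 fell aerobically (9 and 3 adjusted over the list alone), and recA was at 0.08.

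A candidate explanation for the early rise of gcvB and the glycine cleavage genes is glycine freed from the glycinate ligand. The test asked whether other GcvB targets, chosen without regard to their values, were lower early with iCORM-3. In aerobic cultures the median of 6 such targets at 2.5 to 10 min was -0.57 (both cultures below 0), and 0 of 10000 random lists of 6 genes were lower. Such a fall would follow a rise of gcvB from any cause, so it cannot tell whether glycine was that cause. It also does not bear on why the glycine cleavage genes rose. In anaerobic cultures with iCORM-3 their median was -0.01, with members on both sides of 0, and 28.9% of random lists were lower. No such fall of these targets was seen there, although gcvB rose in that arm. In anaerobic cultures with CORM-3 their median was -0.46 (both cultures below 0) and 0.01% of random lists were lower, although many other genes also fell with CORM-3. Random lists take genes as independent, while the 6 targets may move together, so these shares do not measure the spread over cultures. Glycine itself was not measured.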
